A study of Mus musculus with 6 samples.

How the data were processed

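The series holds 6 iCLIP libraries from C2C12, an immortalised mouse muscle precursor line that grows as single myoblasts and fuses into multinucleate myotubes when serum is lowered. In iCLIP, ultraviolet light fixes proteins to the RNA they touch, an antibody pulls down the protein, and sequencing of the attached fragments shows where on the transcripts it sat. Per the labels' protocols, cells were irradiated with 400 mJ, and complexes were radiolabelled, separated on a gel, transferred to nitrocellulose and digested with proteinase. The libraries fall into 5 groups by antibody and cell stage. They are anti-PanQk in myoblasts (1 library), anti-PanQk in myotubes after 72 h of differentiation (2 libraries), anti-Qk6 in myoblasts (1), anti-Qk7 in myoblasts (1) and an anti-HA control in myoblasts (1).

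The analysis rests on 2 peak lists, 1 from the anti-PanQk myoblast library and 1 from the anti-HA control library. Each list was assigned to its library by the library name in its track line. The myotube, Qk6 and Qk7 libraries were not analysed here, so neither differentiation nor the isoforms could be compared. With 1 library per antibody there are no replicates. Every test therefore compares these 2 lists, not 2 replicated conditions, and intervals cover counting error only.

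Peaks were called with CLIPper on 1 library each, on the mm9 build, per the file headers, which also carry the tags rptfilt and premRNA without saying what they mean. Bowtie2, TopHat and mm9 are named in the submitters' processing notes. Versions are not given in the sources used here. The p-value of each peak is the one the authors deposited, and every deposited p-value was at most 0.0199 in the control list and 0.0210 in the anti-PanQk list. The last part of each deposited peak name was taken as the number of reads in the peak. The smallest was 3 reads in both lists. The deposited p-values followed this number closely: at 3 reads all lay between 0.0190 and 0.0210, and at 4 reads between 0.00366 and 0.00424, over both lists. The p-value thus carried little beyond the read number, and it underflowed to 0 for 79 control and 80 anti-PanQk peaks. Peak names also carry a running number per gene. These numbers add up to at least 13910 clusters in the control genes and 36543 in the anti-PanQk genes, of which at most 61.1% and 61.5% were listed. The depth of the libraries is unknown. The listed intervals hold 150162 reads in the control and 200878 in the anti-PanQk list, which is the sum over called peaks only, so read numbers are given as listed and were not scaled between lists.

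Genes appear in the lists as Ensembl gene IDs without symbols, and the reference table given with the data pairs none of them with a symbol. Loci are therefore described by their mm9 position, 1-based, and a locus is the stretch from the first to the last peak listed under 1 gene ID in either list. It is not the annotated gene. Gene lists fixed before the data were examined could not be matched to these IDs, so none was tested. Sequence motifs and transcript regions need an mm9 genome and annotation and were likewise not analysed.

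Overlap was counted with bedtools 2.31.1 and Python 3.11.15 (pandas 2.3.3, numpy 2.4.6, scipy 1.17.1), on the same strand, with 1 nt shared as the minimum. An anti-PanQk peak that no control peak overlapped is called control-free. Entries were counted as listed, which includes 322 anti-PanQk and 210 control entries that repeat an interval under another gene ID. Shares have exact Clopper-Pearson 95% intervals. Observed overlap was set against 1000 seeded shuffles of each anti-PanQk peak within its locus, for loci of at least 1000 nt. Chromosome shares were compared by two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 22 chromosomes. The code of the overlap count was run on 22488 simulated peaks, 2000 placed exactly on control peaks and the rest moved where no control peak lies. It recovered 100.0% of the 2000 with 0 false calls, which any working count must give. A list drawn at random inside the loci, by the same draw as the shuffles, lay within the range of 100 shuffles. These runs check the code only and carry no evidence about the real lists.

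The rule for named loci was fixed together with the gene lists. It takes the 12 gene IDs whose control-free peak had the lowest p-value, the 8 with the most control-free peaks and the 5 with the most control peaks, 25 in all. The parts of the rule that need gene symbols could not be applied. Alternatives fixed with it were a p-value of at most 1e-06, an overlap of 50% of the shorter peak, a distance of 100 nt, strand ignored, equal list lengths, removal of every gene with a control peak and merging of peaks within 50 nt. Others were added after seeing the data: each interval counted once, no mitochondrial chromosome, no control peaks of 10 to 26 reads, no genes with 100 or more peaks (for the X chromosome), and peaks shifted by 100 to 500 nt in place of the shuffles. The splits by reads per peak, by chromosome and by position in the locus were also chosen after seeing the data.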

Results

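The series set out to find the transcripts that Quaking (Qk) proteins contact directly in muscle cells. Qk proteins are RNA-binding proteins that act in splicing, transcript stability and translation. The 2 lists compared were both from proliferating C2C12 myoblasts. One came from an antibody that recognises the Qk proteins together (anti-PanQk). The other came from an antibody against HA, a viral peptide tag, and gave the background. The anti-PanQk list held 22488 peaks under 7135 gene IDs, and the control list held 8496 peaks under 4497 gene IDs, a ratio of 2.65 anti-PanQk entries per control entry. The listed peaks held 200878 reads in the anti-PanQk and 150162 in the control list, and the depth of the libraries is unknown. Neither library had a replicate.

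Most anti-PanQk peaks lay where the control list had none. Of the 22488 peaks, 19333 were control-free (86.0%, 95% interval 85.5 to 86.4), and they fell under 6620 gene IDs. The other 3155 (14.0%, 13.6 to 14.5) overlapped a control peak. In the opposite direction, 2503 of the 8496 control peaks (29.5%, 28.5 to 30.4) overlapped an anti-PanQk peak. The order of the 2 shares turned with p at most 1e-06 (31.7% of anti-PanQk and 19.1% of control peaks) and with the anti-PanQk list limited to as many peaks as the control holds (30.8% and 25.7%). Each share depends on the length of its own list, and p at most 1e-06 left 4370 anti-PanQk and 6189 control peaks. Without control peaks of 10 to 26 reads, a setting chosen after seeing the data, the shares were 8.55% and 45.6%. On the opposite strand overlap was rare: 8 anti-PanQk peaks (0.0356%, 0.0154 to 0.0701) overlapped a control peak there. Every peak is listed under a gene ID, and how often genes lie on both strands at the same place was not determined. The low share is therefore no measure of background.

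By gene, 3736 IDs carried peaks in the anti-PanQk list only, 3399 in both lists and 1098 in the control list only. Of the 3399 shared IDs, 2893 had at least 1 control-free anti-PanQk peak, and in 506 every anti-PanQk peak was overlapped. Control-free peaks were spread thinly. A single such peak was found in 3007 IDs (45.4% of those with any), and 278 IDs (4.20%) had 10 or more and held 23.5% of all control-free peaks. The counts depended on how weak a peak was admitted. Of the 19333 control-free peaks, 2403 under 1153 IDs had p at most 1e-06. With that limit on both lists the count was 2985 under 1340 IDs, since 582 peaks that overlapped a weaker control peak then counted as control-free. When the anti-PanQk list was limited to as many of its strongest peaks as the control list holds, 5875 under 2587 IDs were left. The gene split turned in both settings, to 697 IDs in the anti-PanQk list only and 2561 in the control list only with the stricter p-value, and to 1149 and 2524 with equal list lengths. The stricter p-value left 4370 anti-PanQk and 6189 control peaks. The gene split widened without control peaks of 10 to 26 reads, to 5536 and 445, with 1599 IDs in both lists.

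The 2 lists shared positions more often than shuffled peaks did. Among 17915 anti-PanQk peaks in loci long enough to shuffle, 2070 overlapped a control peak, against a median of 299 and a highest value of 356 in 1000 shuffles (permutation p = 0.000999, the smallest these shuffles can give). The ratio was 6.92. Shuffles ignored exons, and with peaks instead shifted by 100 to 500 nt the median rose to 865 and the ratio fell to 2.39, again with every draw below the observed count (highest 938).

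Strong anti-PanQk peaks were the ones most often found in the control as well. The overlapped share was 2.72% (2.41 to 3.07) of the 9802 peaks with 3 reads and 7.54% (6.87 to 8.26) of the 5635 with 4 or 5 reads. It was 38.5% (36.7 to 40.3) of the 2872 with 10 to 26 reads and 79.5% (75.3 to 83.3) of the 420 with more than 50 reads. Control-free anti-PanQk peaks had a median of 4 reads (quartiles 3 and 5), against 12 (6 and 25) for the overlapped ones, and 86 control-free peaks had more than 50 reads. Control peaks did not follow the same course. Their overlapped share was 35.4% (33.0 to 37.8) at 3 to 5 reads, 20.1% (18.99 to 21.2) at 10 to 26 reads and 92.8% (88.7 to 95.7) above 50 reads.

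**Figure D1:**
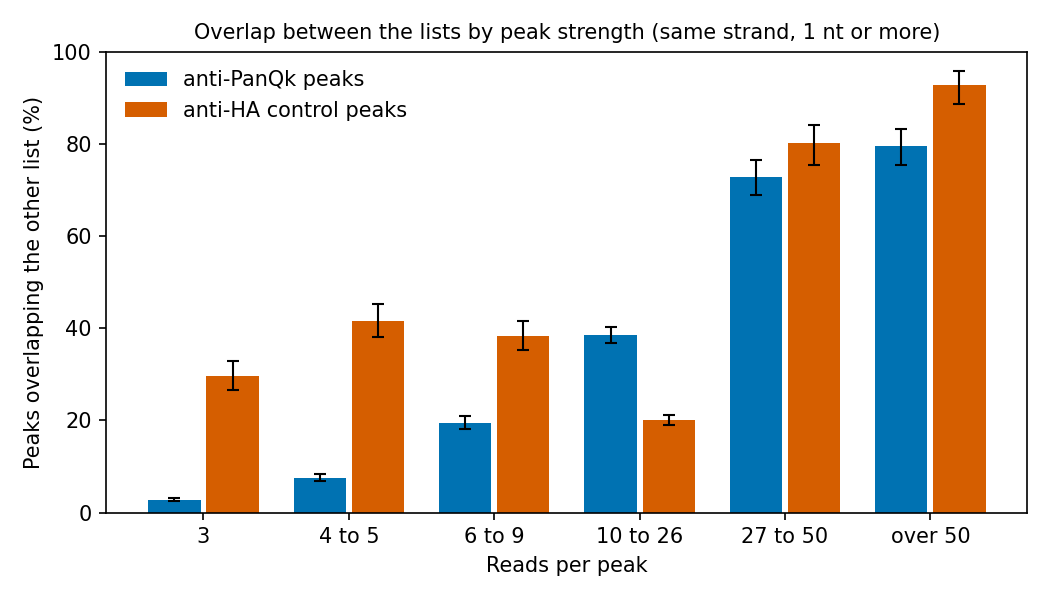
Share of peaks (%) that overlap a peak of the other list on the same strand, by reads per peak, for anti-PanQk (blue) and anti-HA control (orange) peaks, with exact 95% intervals as bars. The anti-PanQk share rises from 2.72% at 3 reads to 79.5% above 50 reads, while the control share drops to 20.1% at 10 to 26 reads.

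The lists also differed in reads per peak as listed, which are not scaled for the unknown depth. The anti-PanQk list was made mostly of weak peaks, with a median of 4 reads (quartiles 3 and 7), and 43.6% of its peaks had 3 reads. The control list had a median of 15 reads (quartiles 8 and 19), and 63.2% of its peaks had 10 to 26 reads, against 12.8% in the anti-PanQk list. The control histogram had a second mode at 18 reads (571 peaks) beyond a low point at 8 reads (210 peaks), whereas the anti-PanQk histogram was highest at 3 reads and had no second mode. Peaks were wider in the anti-PanQk list, with a median of 32 nt (quartiles 10 and 45) against 22 nt (9 and 42). An anti-PanQk gene ID carried a median of 2 peaks, and 337 IDs had 10 or more, while a control ID carried a median of 1, and 60 had 10 or more.

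**Figure D2:**
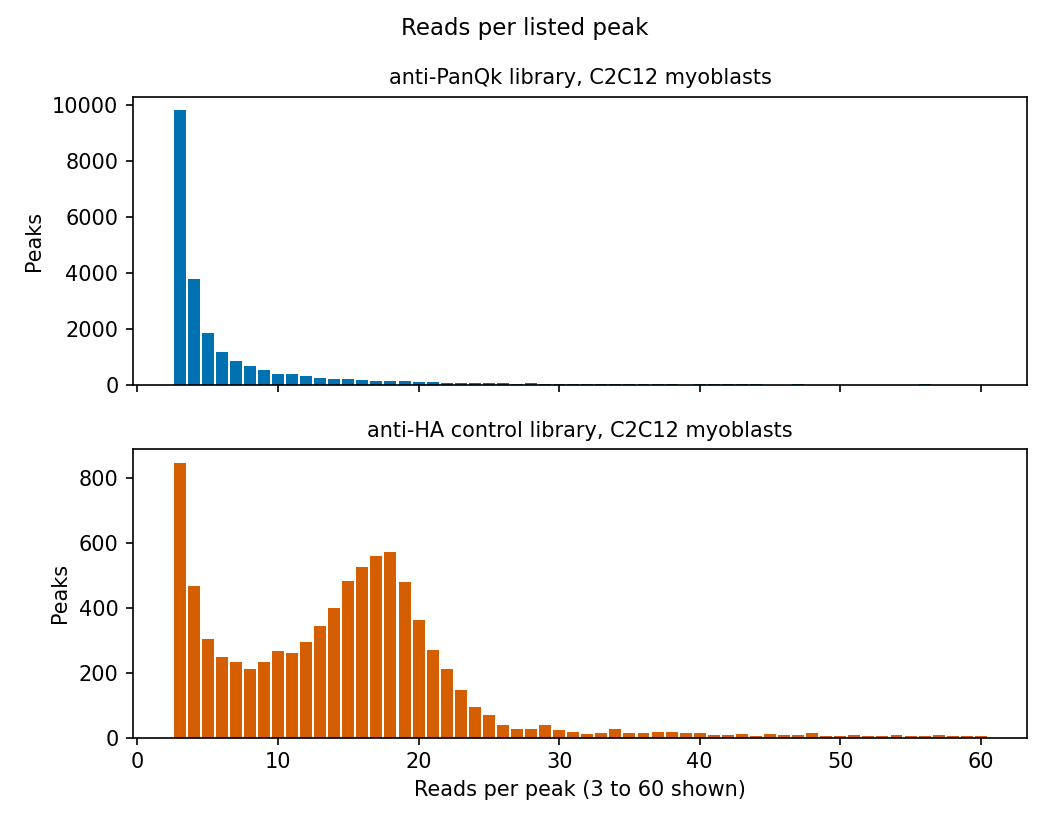
Number of peaks (vertical axis) by reads per peak (horizontal axis, 3 to 60 reads shown) in the anti-PanQk list (top) and the anti-HA control list (bottom), with separate vertical scales. The anti-PanQk histogram is highest at 3 reads (9802 peaks), and the control numbers have a second mode at 18 reads.

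The loci with the most control-free peaks carried groups of weak peaks, with a median of 4 to 7 reads per control-free peak, mostly near the downstream end of the stretch covered by peaks. The highest number, 63 of 85 peaks, was under ENSMUSG00000017466 on the minus strand of chromosome 11 (118162388 to 118216607), and 61 of the 63 lay in the last 10% of that stretch. A locus on the plus strand of chromosome 16 (24398125 to 24992242) had 57 control-free peaks of 62, with 46 in the last 10%. A locus on the minus strand of chromosome 17 (10399353 to 10511753) had 55 of 59, with 48 in the last 10% and its strongest, of 31 reads, at 10399353 to 10399490. A locus on the plus strand of chromosome 5 (93540865 to 93603964) had 54 of 60, with 51 in the last 10%. The control list had 10, 8, 6 and 6 peaks at these 4 loci, with at most 22, 21, 19 and 19 reads. Of the control-free peaks at the 4 loci, 4, 6, 20 and 20 had p at most 1e-06. With equal list lengths 30 were left under ENSMUSG00000017466 and 19 at the chromosome 16 locus, and under ENSMUSG00000017466 29 of the 63 lay more than 100 nt from a control peak.

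A pair of loci of this kind lay on the X chromosome and also carried strong overlapped peaks. The locus at 93291456 to 93363888 on the plus strand had 51 control-free peaks of 134 and 19 control peaks, and the locus at 53985016 to 54046508 on the plus strand had 50 of 142 and 27 control peaks. Of these control-free peaks, 9 and 14 had p at most 1e-06, and 15 and 11 lay more than 100 nt from a control peak. The 51 at the first of these loci became 20 with equal list lengths and 81 without control peaks of 10 to 26 reads. A locus on the minus strand of chromosome 1 (71632110 to 71699687) had 50 anti-PanQk peaks and no control peak, with 13 of the 50 in the last 10% and the rest spread along 67.6 kb. Some of the 50 abut without a gap, such as 71632357 to 71632408 and 71632409 to 71632439, as do some at the chromosome 17 locus. The numbers per locus therefore count listed peaks and not separate sites. A locus on the minus strand of chromosome 13 (3882180 to 3902260) had 49 control-free peaks and 2 control peaks. None of its 49 lay in the last 10%, and its strongest, of 22 reads, lay at the upstream end (3902189 to 3902260). At p at most 1e-06 were 14 of the control-free peaks at the chromosome 1 locus and 15 at the chromosome 13 locus.

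**Figure D3:**
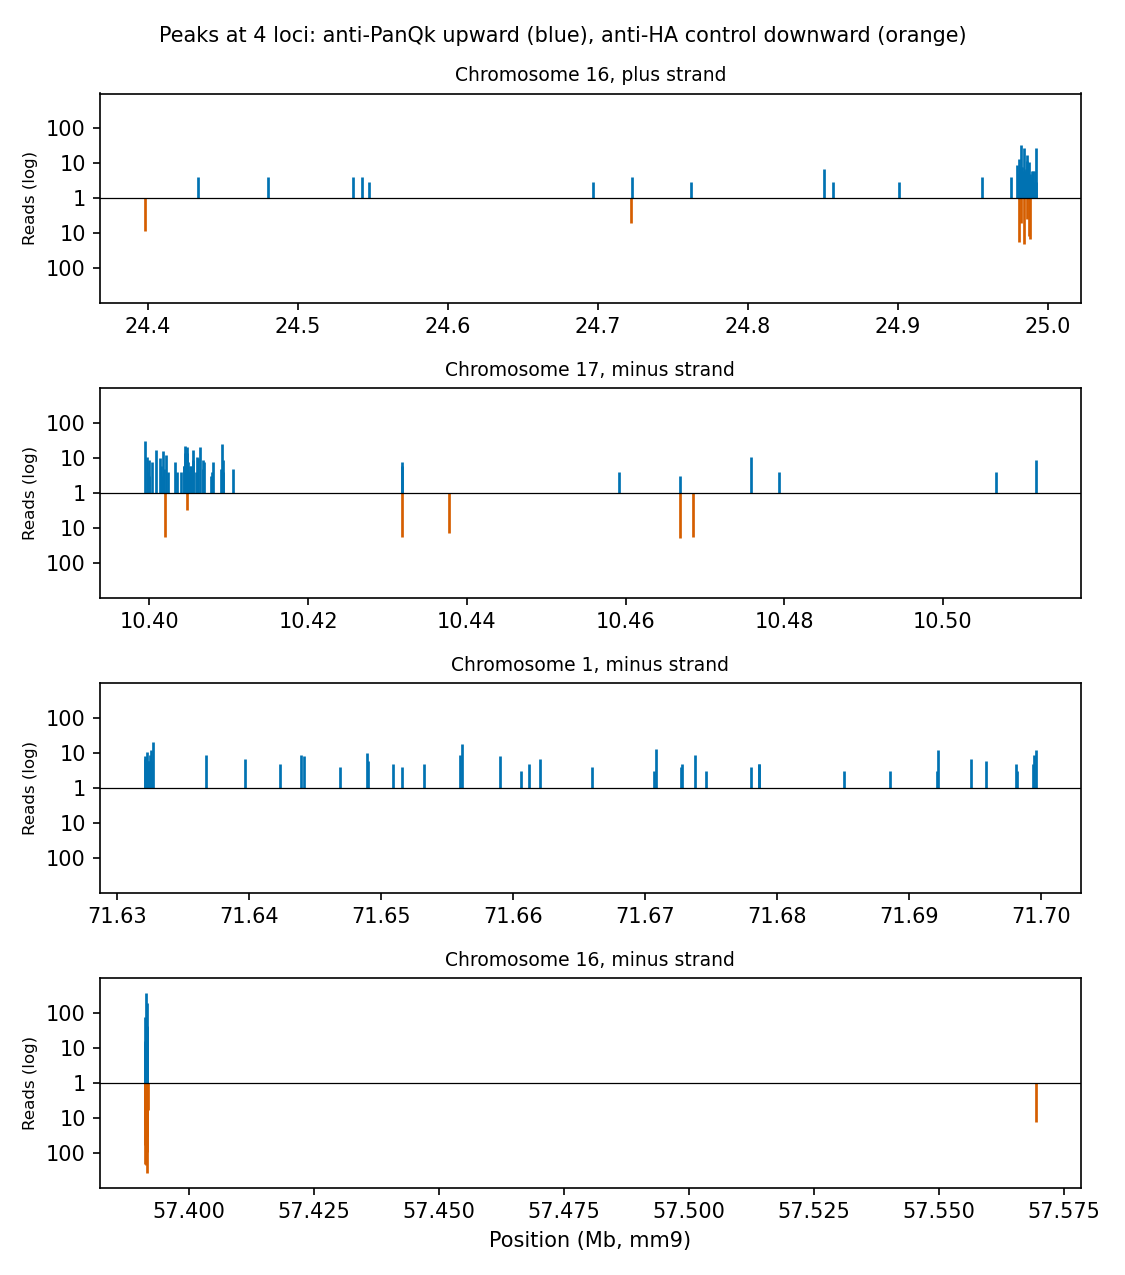
Peaks at 4 loci on mm9, with position in Mb on the horizontal axis and reads per peak on a log axis, anti-PanQk upward in blue and anti-HA control downward in orange; the direction of transcription is the strand in each title. The loci on chromosomes 16 (plus strand), 17 and 1 carry 62, 59 and 50 anti-PanQk peaks against 8, 6 and 0 control peaks, and the chromosome 16 locus on the minus strand carries 26 against 44. At the last locus all peaks but 1 control peak lie between 57391239 and 57391791.

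The 12 loci picked for the lowest p-value of a control-free peak were of another kind. Of these, 4 were on the mitochondrial chromosome, 10 carried control peaks under the same ID, and in 10 the strongest control-free peak lay within 100 nt of a control peak. The lowest p-value was 2.65e-210, for a peak of 124 reads at positions 161 to 165 of the mitochondrial chromosome under ENSMUSG00000064337, where 34 control peaks were listed. On chromosome 3, 3 short loci had nearly equal listed read numbers, unscaled for depth, in both lists: 123 and 126 reads at 96263960 to 96264104, 117 and 116 at 96132376 to 96132483, and 116 and 115 at 96254397 to 96254511 for the strongest anti-PanQk and control peaks. At each of these loci the anti-PanQk and the control peak compared lay toward opposite ends and did not overlap. With control peaks within 100 nt counted as overlapping, 8 of the 12 had no control-free peak left. The exceptions with no control peak under their ID were a locus on chromosome 1 (177834675 to 177834727), with 4 peaks of at most 112 reads, of which 2 had p at most 1e-06, and a locus on chromosome 18 (47060454 to 47060491), with 3 peaks of at most 98 reads, of which 2 did.

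The loci richest in control peaks had few control-free anti-PanQk peaks, with 2 exceptions. ENSMUSG00000010342 on the plus strand of chromosome 11 (87236368 to 87285058) had 75 control and 70 anti-PanQk peaks, of which 17 were control-free and 1 lay more than 100 nt from a control peak. ENSMUSG00000022748 on the minus strand of chromosome 16 (57391239 to 57569381) had 44 and 26, of which 1 was control-free, with at most 391 reads in the control and 376 in the anti-PanQk list. All of its peaks lay between 57391239 and 57391791 except 1 control peak at 57569359 to 57569381, which alone sets the length of the locus. On chromosome 9, the locus at 56051445 to 56162631 on the minus strand had 41 control and 31 anti-PanQk peaks, of which 3 were control-free, and the locus at 123370916 to 123371304 on the plus strand had 40 and 20, of which 0 were. On the plus strand of chromosome 19 (9063774 to 9094448), 33 of 44 anti-PanQk peaks were control-free beside 38 control peaks, and 6 of the 33 had p at most 1e-06. Without control peaks of 10 to 26 reads, a setting chosen after seeing the data, the control-free peaks numbered 26 under ENSMUSG00000010342, 6 under ENSMUSG00000022748, and 12 and 4 at the chromosome 9 loci, and the control peaks of the chromosome 19 locus fell to 8.

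Mitochondrial transcripts gave a smaller share of the anti-PanQk peaks, but a larger share of the strong ones. The mitochondrial chromosome held 414 anti-PanQk peaks (1.84%, 1.67 to 2.03) and 235 control peaks (2.77%, 2.43 to 3.14; Fisher's exact test, adjusted p = 2.0e-05). The order turned with p at most 1e-06 in both lists, at 6.75% of anti-PanQk and 2.38% of control peaks, and with equal list lengths, at 4.35% and 2.77%. It also turned in reads, at 8.61% of the anti-PanQk and 3.87% of the control reads in peaks. Without control peaks of 10 to 26 reads, a setting chosen after seeing the data, the shares were 1.84% and 4.80% of peaks. Both lists put nearly all mitochondrial peaks on the plus strand (406 of 414 and 223 of 235), and 221 of the 414 (53.4%) overlapped a control peak. The 414 and 235 mitochondrial peaks fell under 31 and 32 gene IDs, and the tests by peak take the peaks of a gene as independent. Of the 22 chromosomes, 7 passed 0.05 after adjustment when compared by peak (Fisher's exact test). Besides the mitochondrial and X chromosomes these were chromosomes 7, 8, 9, 10 and 19. Chromosome 10 had the larger share in the anti-PanQk list, and chromosomes 7, 8, 9 and 19 in the control list. The comparison by gene set IDs in the anti-PanQk list only against all control IDs, and so left shared IDs out of the anti-PanQk side. There only the mitochondrial chromosome passed, with 2 of 3736 IDs against 32 of 4497. With shared IDs kept, the mitochondrial chromosome held 31 of 7135 anti-PanQk and 32 of 4497 control IDs, which was not tested. The X chromosome held 4.64% (4.37 to 4.93) of anti-PanQk and 3.48% (3.10 to 3.90) of control peaks (Fisher's exact test, adjusted p = 6.1e-05), a test that takes the peaks of a gene as independent. Its 3 genes with 100 or more peaks over both lists held 365 of the 1044 anti-PanQk and 58 of the 296 control peaks. Without the 9 such genes on any chromosome, a setting chosen after seeing the data, the shares were 3.15% (2.92 to 3.39) and 2.88% (2.53 to 3.27), and the difference did not pass (Fisher's exact test, unadjusted p = 0.245). By gene, the X chromosome held 152 of the 3736 IDs in the anti-PanQk list only (4.07%). It held 139 of the 4497 control IDs (3.09%). That difference passed before adjustment over the chromosomes but not after it (Fisher's exact test, unadjusted p = 0.0193, adjusted p = 0.212). With shared IDs kept, the X chromosome held 250 of the 7135 anti-PanQk IDs, a share that was not tested against the control.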

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

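The settings chosen after seeing the data were each interval counted once, no mitochondrial chromosome, no control peaks of 10 to 26 reads, no genes with 100 or more peaks, and shifted peaks. The lists hold 1 library each, so no library could be left out. No paired analysis was possible because each group analysed has a single library. The alternatives for motifs, transcript regions and gene lists were not run, as these results were not computed. The main counts were 19333 control-free peaks under 6620 gene IDs. They stayed within 1.5 times those values with an overlap of 50% of the shorter peak, a distance of 100 nt, strand ignored, each interval counted once, no mitochondrial chromosome, and no control peaks of 10 to 26 reads. With p at most 1e-06 they fell to 2985 and 1340 and with equal list lengths to 5875 and 2587, in both cases because fewer peaks were admitted, although the 2985 include 582 that overlapped a weaker control peak in the full list. Removing every gene with a control peak left 3727 IDs. The shares of anti-PanQk and of control peaks that overlap, 14.0% and 29.5%, were 31.7% and 19.1% with p at most 1e-06, 30.8% and 25.7% with equal list lengths, 12.9% and 27.5% with the 50% overlap, 21.8% and 37.99% within 100 nt, 13.3% and 28.4% without the mitochondrial chromosome, and 8.55% and 45.6% without control peaks of 10 to 26 reads. The order of the 2 shares thus turned with the stricter p-value, which left 4370 anti-PanQk and 6189 control peaks, and with equal list lengths. The cause of the other differences was not tested. Median reads were 15 (anti-PanQk) and 17 (control) with p at most 1e-06, against 4 and 15. Merging peaks within 50 nt gave 3 for anti-PanQk. A merged peak kept only the reads of its strongest part, so this value does not give the reads of whole merged peaks. Leaving out control peaks of 10 to 26 reads gave a median of 5 for the control. Median widths were 49 and 20 nt with the stricter p-value and 34 and 27 nt after merging, against 32 and 22, and the control median was 23 nt without the mitochondrial chromosome. The overlap over chance was 2.39 with shifted peaks against 6.92 with shuffles. Of the 25 named loci, the number of control-free peaks moved by over 1.5 times at 15 with the distance of 100 nt (all lower, 10 of the 25 then at 0, of which 1 was at 0 before), at 14 with the stricter p-value (12 lower), at 9 with equal list lengths (all lower, 3 of the 25 then at 0, of which 1 was at 0 before), at 5 without control peaks of 10 to 26 reads (none lower), at the 4 mitochondrial loci without that chromosome, and at 1 with the 50% overlap (higher). Library depth is unknown, so a missing peak in either list is no evidence that a site was not bound.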

Other observations

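The comparisons of position in the locus, of spacing and of single genes, and the shifted peaks, were chosen after seeing the data, as was the range of 10 to 26 reads, which was read from the histogram. Peaks gathered toward the downstream end of loci in both lists. Among genes with at least 5 peaks over at least 5000 nt, leaving out the 2 outermost peaks that set the stretch, 51.1% of 7825 anti-PanQk peaks in 965 genes (95% interval 50.0 to 52.2) lay in the last 10%, against 39.7% of 1098 control peaks in 147 genes (36.8 to 42.7). The first 10% held 6.29% (5.76 to 6.85) and 10.3% (8.56 to 12.2). In 382 of the 965 anti-PanQk genes (39.6%, 36.5 to 42.8) and 43 of the 147 control genes (29.3%, 22.0 to 37.3) the majority of the inner peaks were in the last 10%, and in 27 and 5 they were in the first; the difference was not tested. Peaks of 1 gene are not independent, and the annotation of these ends was not used here. The median distance to the nearest peak on the strand was 819 nt in the anti-PanQk list and 8184.5 nt in the control. Thinned to the control number of 8286 intervals, the anti-PanQk list had a median of 4552.5 to 6684 nt in 100 draws, and 31.5% to 34.1% of its intervals had a neighbour within 500 nt, a range that includes the control share of 31.7%.

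Some genes were skewed toward 1 list. Of 562 genes with at least 10 peaks over both lists, 15 had more anti-PanQk and 21 more control peaks than the overall share of 72.6% gives (exact binomial test, adjusted p under 0.05, a comparison of these 2 lists only). A share of 72.6% leaves less room above it than below it, so the counts of 15 and 21 cannot be set against each other. Of 22 genes with anti-PanQk peaks only, 2 passed. The test takes the peaks of a gene as independent, so its p-values may be too small and the counts of 15 and 21 too high. The clearest on the anti-PanQk side was the minus-strand locus on chromosome 1 with 50 and 0 peaks (exact binomial test, adjusted p = 1.29e-05). On the control side it was a minus-strand locus on chromosome 19 (5796115 to 5802534) with 35 control peaks, where no anti-PanQk peak was listed (exact binomial test, adjusted p = 1.21e-17). RNA abundance alone was taken to leave a variance ratio of the anti-PanQk share near 1. That holds only for independent peaks that rise with abundance alike in both lists, which was not tested. The ratio was 2.79 (bootstrap 95% interval 2.30 to 3.39 over genes), and 2.34 (1.57 to 3.29) with control peaks of 10 or more reads left out. Both intervals lie above the value of 1.5 set for abundance alone, but neither clears the bound of 3 set against it, and peaks within a gene are not independent, so abundance stays open, as does Qk binding, the difference the design names.

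The second mode of the control list may come from single RNA molecules amplified many times, whose barcode was then misread. Per the labels the barcode spans the read start. With the 5 positions written U taken as random, 15 sequences lie 1 substitution away, 16 with the original. The mode at 18 reads lies above these 16. The control list had 559 peaks at 17 reads, 571 at 18 and 479 at 19. Misreading of 1 position in 1 molecule leaves these peaks unaccounted for, while peaks of up to 16 reads stay within it. Peaks from misread single molecules should recur in the other library no more often than the weakest ones. Of the 5370 control peaks in the mode, 20.1% (18.99 to 21.2) overlapped an anti-PanQk peak. The share was 35.4% of the 1614 control peaks of 3 to 5 reads (33.0 to 37.8). The anti-PanQk barcode is written in the same pattern and its list has no second mode, which misreading alone leaves unaccounted for. Background sites in abundant RNA also remain open, since 33.9% of the peaks in the mode were alone in their gene, against 38.8% of those with 3 to 5 reads, while their low overlap goes against it; no biological explanation was tested.

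The overlap above shuffles was not carried by the densest genes. Without the mitochondrial chromosome and the 19 genes with 20 or more control peaks, the observed overlap was still 6.72 times the shuffled median (1613 peaks against 240, highest 284), compared with 6.92 over all loci long enough to shuffle. Only 190 of the 414 mitochondrial peaks were in such loci, with 66 of the 2070 overlaps, so the test bears mainly on the dense genes. Binding sites of the Qk proteins that reach the control library, crosslinked RNA common to both pull-downs, and exons that shuffles ignore could each add to it and were not tested. With shifts of 100 to 500 nt in place of shuffles the ratio was 2.46 without these genes and chromosome (median 657) and 2.39 with them.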
